A study of Mus musculus with 6 samples.

How the data were processed

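RNA was measured in 6 samples of 100 sorted mouse bone marrow HSCs, 3 WT and 3 labelled Piezo1 cKO, by low-input RNA-seq. Per the labels' protocols, RNA was extracted from sorted cells and copied with an oligo(dT) primer and template switching before amplification, without molecular identifiers, so a count is a sequenced fragment or read and not a molecule. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used, with no role or order given, and the genome build was GRCm39. The annotation release is not given in the sources used here. The deposited coordinates were compared with GENCODE M21 on GRCm38: of 19953 genes matched by identifier, 17584 (88.1%) had the same start and end. Coordinates are therefore printed as deposited and read as GRCm38, which conflicts with the build in the notes.

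The table deposited by the authors holds raw counts per gene, not normalized, and FPKM values, which the authors scaled to transcript length and sequencing depth. Low counts were often multiples of 4: between 40.2% and 48.8% of counts from 1 to 40 were, and 4 was the commonest count above 0 in every library. How the counts were made is not given in the sources used here, so count-based precision is likely to be overstated at low counts. The table held 19978 genes, of which 30 lie on chromosome 17; genes outside the table were not analysed here. Gene symbols are those of the table. Near-identical copies and pseudogenes can split the reads of a gene. Gapdh had an FPKM of at most 0.084, and whether split reads are the cause was not tested. Levels of genes with many copies, such as Actg1, Eno1, Rpsa and other ribosomal protein genes, are therefore uncertain.

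Groups were taken from the genotype labels, and total counts ranged from 3907259 to 72116120. Genes were tested if their FPKM was at least 1 in at least 3 of the 6 libraries, whichever the genotype, which left 4173. The design written before the data were examined used limma on log2(FPKM + 1) and named edgeR in its place if the table held raw counts. Because it holds both, edgeR's quasi-likelihood test on the deposited counts (edgeR 4.0.16, TMM scaling, R 4.3.3) was the main gene test and limma 3.58.1 the alternative, both with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors of edgeR fold changes were taken as the fold change over the square root of its F statistic. DESeq2 1.42.0 was an alternative, run with a local fit of its dispersion trend. Gene lists were tested with camera on log2(FPKM + 1), with a pseudocount of 1, a preset inter-gene correlation of 0.01 and a variance trend, adjusted over the lists with at least 5 tested genes, and list medians are on that scale. Values of single libraries were compared with two-sided exact permutation tests over the 10 splits of 6 libraries into 3 and 3, whose smallest p is 0.1.

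The genes named were set by a rule: Piezo1; the 12 genes in each direction with the largest change among those past the threshold, with a mean FPKM of at least 5 and no overlap between genotypes, filled by smallest unadjusted p where fewer passed, leaving out predicted and sex-linked genes; up to 4 members of each list with the smallest p; and the sex-linked genes. Since no gene passed, all 24 places were filled by unadjusted p. Some list members that the rule names are not reported here.

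The tests were checked on simulated counts drawn from the means and sizes of these libraries, with 200 of 4173 genes changed. At a low spread (dispersion 0.05), edgeR and DESeq2 recovered 100% of genes changed 4-, 16- or 64-fold, with 9 to 11 false calls for edgeR and 37 to 43 for DESeq2. At the spread of these libraries, edgeR recovered 0% at each fold with 0 false calls, and DESeq2 7%, 33% and 61% with 151, 104 and 159 false calls. The list test reached p under 0.05 in 4% of 50 draws with no shift and in 96% at a log2 shift of 1, for lists of 40 genes simulated as independent. Alternatives covered the pseudocount, filter, scaling, variance model, replicate block, left-out libraries, threshold, count tests and list tests. Further ones were added after seeing the data, among them floors on low counts and the removal of WT 1 and WT 3. Figures were drawn with matplotlib 3.10.9.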

Results

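Transcript levels were measured in hematopoietic stem cells (HSCs), the cells that give rise to all blood lineages, sorted from mouse bone marrow. Each sample held 100 sorted cells, and libraries were made with a low-input method that copies full-length polyadenylated RNA and amplifies it (Smart-seq2). There were 3 wild-type (WT) libraries and 3 libraries labelled Piezo1 cKO, a conditional knockout of Piezo1, which encodes a mechanically gated cation channel. The labels do not say whether the 3 libraries of a genotype came from separate mice, so the p-values measure only the spread between these samples, which may be technical. The comparison asks how the loss of Piezo1 alters the transcriptome of HSCs. The table held counts and FPKM values for 19978 genes. Total counts were 18035239 in WT 1, 64794532 in WT 2 and 3907259 in WT 3, against 31252820, 72116120 and 69972499 in the libraries labelled Piezo1 cKO 1, 2 and 3, an 18.5-fold range.

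The libraries also differed in how evenly their counts were spread over genes. The 100 most abundant genes took 46.1% of the counts in WT 1, 30.2% in WT 2 and 76.1% in WT 3, and between 29.8% and 31.7% in the labelled cKO libraries. Genes at an FPKM of at least 1 numbered 4748 ± 1422 (SD, n = 3) in WT and 4023 ± 774.5 (SD, n = 3) in the labelled cKO, a difference within the spread (two-sided exact permutation test, p = 0.6; 3 against 3 libraries cannot give a p below 0.1). That order turned at a cutoff of FPKM 5, with 2329 ± 1604 genes in WT and 3032 ± 822.7 in the labelled cKO (SD, n = 3; exact permutation p = 0.5).

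**Figure D1:**
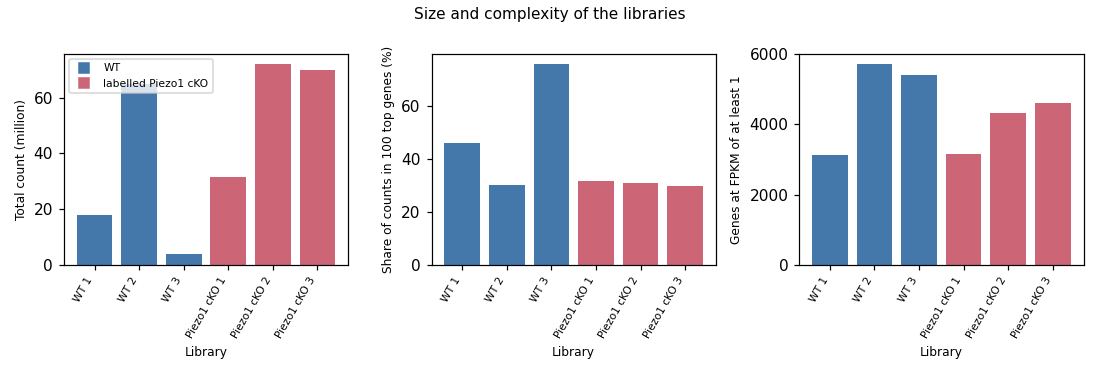
Total count, share of counts in the 100 most abundant genes in percent, and number of genes at an FPKM of at least 1, one bar per library, WT in blue and labelled Piezo1 cKO in red. WT 3 has the smallest total, 3907259, and the highest share in 100 genes, 76.1%.

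Expression profiles did not separate by genotype. Over the 4173 genes tested, Pearson's r of log2(FPKM + 1) between libraries, taken across genes, which are not independent replicates, averaged 0.416 within a genotype and 0.388 between genotypes. WT 2 correlated at 0.60 and 0.61 with the libraries labelled cKO 2 and cKO 3, and at 0.37 and 0.26 with WT 1 and WT 3. The first principal component held 42.6% of the variance and placed WT 2, labelled cKO 2 and labelled cKO 3 at 82.3 to 86.6 and the other libraries at -102.1 to -51.0 (exact permutation test for genotype, p = 0.2).

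**Figure D2:**
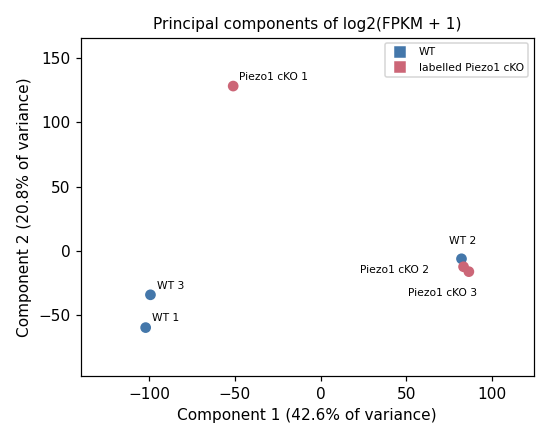
First and second principal components of log2(FPKM + 1) over the tested genes, in arbitrary units, one point per library. WT 2 lies at 82.3 on component 1, beside labelled cKO 2 at 83.5 and labelled cKO 3 at 86.6, while WT 1 and WT 3 lie at -102.1 and -99.3.

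Piezo1 itself did not follow the labels. Piezo1 (ENSMUSG00000014444; chromosome 8, 122481698 to 122551329, coordinates as deposited, which match GRCm38) had an FPKM of 0.539, 3.97 and 1.57 in WT 1, 2 and 3 and of 0.175, 8.81 and 0.819 in the labelled cKO 1, 2 and 3. The highest level was in a library labelled cKO, with 6974 counts. Group means were 2.03 ± 1.76 in WT and 3.27 ± 4.81 in the labelled cKO (SD, n = 3; exact permutation p = 1). The log2 fold change was 1.20 with a standard error of 2.21 (edgeR, adjusted p = 0.843), and it turned to -1.65 without labelled cKO 2. The median over all tested genes in the same fit was 1.1, so 1.20 is not a rise particular to Piezo1. It also turned negative with median-of-ratios scaling. Which exons were deleted is not in the labels, and counts from exons that remain would still be assigned to the gene. Genotypes are therefore named below as the libraries were labelled, and every direction rests on those labels.

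No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. An unadjusted p under 0.05 was reached by 287 genes, 142 higher and 145 lower in the labelled cKO, where 209 would be expected by chance. That count ranged from 155 to 705 without one library, and with median-of-ratios scaling it was 377, 150 higher and 227 lower. limma on log2(FPKM + 1) called 0 genes, with 199 at an unadjusted p under 0.05, 116 higher and 83 lower. DESeq2 called 298 genes, 135 up and 163 down, and gave no adjusted p to 752 of the 4173 genes. In data simulated with the spread of these libraries, DESeq2 made 104 to 159 false calls. In the same simulations edgeR recovered 0% of genes changed 64-fold, so a count of 0 does not show that no gene changed. The biological coefficient of variation was 1.49. Groups did not overlap for 482 genes, 11.6% of those tested, where chance gives 10%.

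The 24 genes in the next sentences were chosen by smallest unadjusted p among genes whose genotypes did not overlap, so that separation is how they were selected and not a finding. None passed the threshold in edgeR (adjusted p of 0.533 for Cc2d1b and 0.692 for each of the others). Of those higher in the labelled cKO, Wfdc17, a secreted protein of myeloid cells, had a mean FPKM of 1980 ± 1170 against 14.6 ± 15.2 in WT (SD, n = 3). Ms4a6c had 187 ± 175 against 0.519 ± 0.444, and Brix1, a ribosome assembly factor, 185 ± 172 against 1.68 ± 1.25. Map2k5, the kinase MEK5, had 60.1 ± 21.3 against 0.222 ± 0.0765, and Mrps17, of the mitochondrial ribosome, 38.0 ± 27.9 against 0.198 ± 0.136. Commd1 had 76.2 ± 50.9 against 0.589 ± 0.475, the noncoding RNA Dancr 77.8 ± 73.5 against 0.119 ± 0.0666, and the exocyst subunit gene Exoc4 26.0 ± 30.7 against 0.149 ± 0.183. Poglut1 had 122 ± 151 against 0.547 ± 0.658 and Zfp593 31.5 ± 31.6 against 0.313 ± 0.485. Cyren and Loxl3 were listed at 0 in WT 2 and WT 3, with 4 and 8 counts in WT 1, and had an FPKM of 19.8 ± 13.8 and 14.3 ± 16.4 in the labelled cKO.

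Among the genes lower in the labelled cKO, most of the WT mean came from 1 or 2 libraries. Fen1, a nuclease of DNA replication, had an FPKM of 527, 15.6 and 1.43 in WT 1, 2 and 3, and 0.677 or less in the labelled cKO. Cc2d1b had 462, 11.2 and 1.65 in WT, Bpnt1 438, 5.84 and 1.62, Dck (deoxycytidine kinase) 84.7, 2.18 and 1.31, and Rpp25l 156, 4.13 and 3.57. Atp6ap2, an accessory protein of the proton pump, had 2.17, 89.5 and 2150 in WT 1, 2 and 3, against 1.83 or less in the labelled cKO. It is among the 20 loci with outsized counts in WT 3 that are described at the end. Cd48, a surface receptor of the SLAM family, had 110 in WT 2 against 1.47 and 2.02 in the other WT libraries, and Mrpl53 had 251 against 1.11 and 1.00. Timm50, of the mitochondrial import channel, had 11.6 ± 7.99 in WT and 0.111 ± 0.0694 in the labelled cKO (SD, n = 3). Hsdl1 had 18.5 ± 15.2 against 0.0817 ± 0.103, Nenf 51.2 ± 53.8 against 0.406 ± 0.507, and Cbr1, a carbonyl reductase, 19.5 ± 28.0 against 0.111 ± 0.102. Values of FPKM 1 to 5 in WT 3 stood on 5 to 46 counts for these genes.

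Of the 33 gene lists fixed before the data were examined, 26 had at least 5 tested genes, and camera with its preset correlation called 2. Lists with fewer got no list test at this filter. Among them were mechanosensitive channels and YAP/TAZ targets, with 2 tested genes of 24 in the table. TGF-beta, BMP and SMAD genes (3 tested), stromal and endothelial markers (4) and antigen presentation genes (2) were also left out. With no filter beyond a value above 0, the mechanosensitive list had a median of -0.35 over 24 genes and did not pass (camera, downward, adjusted p = 0.071). Antigen presentation had 0.01 over 6 genes in that setting (camera, adjusted p = 0.832). No member of the 26 tested lists passed over all genes tested or adjusted over the list alone (edgeR, 0 genes in each case). The sex-linked genes were also fixed in advance but were not counted among these lists and got no list test. The erythroid list fell in the labelled cKO, with a median log2 difference of -1.72 over 10 genes (camera, adjusted p = 0.0343), and 3 of its members had a positive difference. With an estimated correlation, camera gave each of the 26 lists an adjusted p of 0.959. That value, repeated below for other lists, therefore does not set one list apart from another. The estimated correlation of the erythroid list was 0.03, with an unadjusted p of 0.048 (camera). Its 4 globin genes, which encode the chains of hemoglobin, had each WT value above each labelled cKO value. Hbb-bs had an FPKM of 4080, 6460 and 14000 in WT against 1640, 828 and 702. Hbb-bt had 3290, 2880 and 5820 against 831, 537 and 759. Hba-a1 had 1160, 1940 and 1100 against 117, 319 and 62.1, and Hba-a2 1340, 2700 and 904 against 215, 430 and 94.5. The pairs Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical copies, so the split within a pair is uncertain. Globin took 1.439 ± 0.751% of counts in WT and 0.184 ± 0.0595% in the labelled cKO (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible). Without the globin genes the list had a median of 0.33 and an adjusted p of 0.861 (camera). The call also ended without WT 2 (adjusted p = 0.0887) and without each labelled cKO library in turn (0.116, 0.151 and 0.214). It ended too with the replicate block (0.0818), median-of-ratios scaling (median -0.75, 0.0643) and array weights (0.171).

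The oxidative phosphorylation list, the nuclear genes of the respiratory chain, rose in the labelled cKO, with a median log2 difference of 1.26 over 68 genes, 57 of them positive (camera, adjusted p = 0.0343; adjusted p = 0.959 with an estimated correlation of 0.40). Cox4i1, of cytochrome c oxidase, had an FPKM of 44.9, 422 and 45.5 in WT against 539, 1060 and 890, and Sdhc, of succinate dehydrogenase, 1.15, 2.83 and 3.69 against 21.0, 36.3 and 22.9. Cox6b1 had 16.9, 2290 and 62.9 in WT against 2960, 2660 and 1880, and Uqcrfs1 10.9, 1.18 and 24.5 against 348, 0.713 and 0.589. Over the tested members the mean log2(FPKM + 1) was 5.37, 8.03 and 3.73 in WT against 6.00, 7.70 and 7.70, lowest in WT 1 and WT 3, the WT libraries with the lowest totals, although Sdhc was low in all 3 WT libraries. Without WT 1 and WT 3, which leaves 1 WT library, the median was -0.71 (chosen after seeing the data), and without WT 3 alone it was 0.02 (camera, adjusted p = 0.78). The call ended as well without each labelled cKO library (adjusted p of 0.0967, 0.19 and 0.214), with the replicate block (0.0818) and with quantile normalization (median 0.42, adjusted p = 0.424). With the total count as covariate, also chosen after seeing the data, the median turned to -0.91 (0.917).

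**Figure D3:**
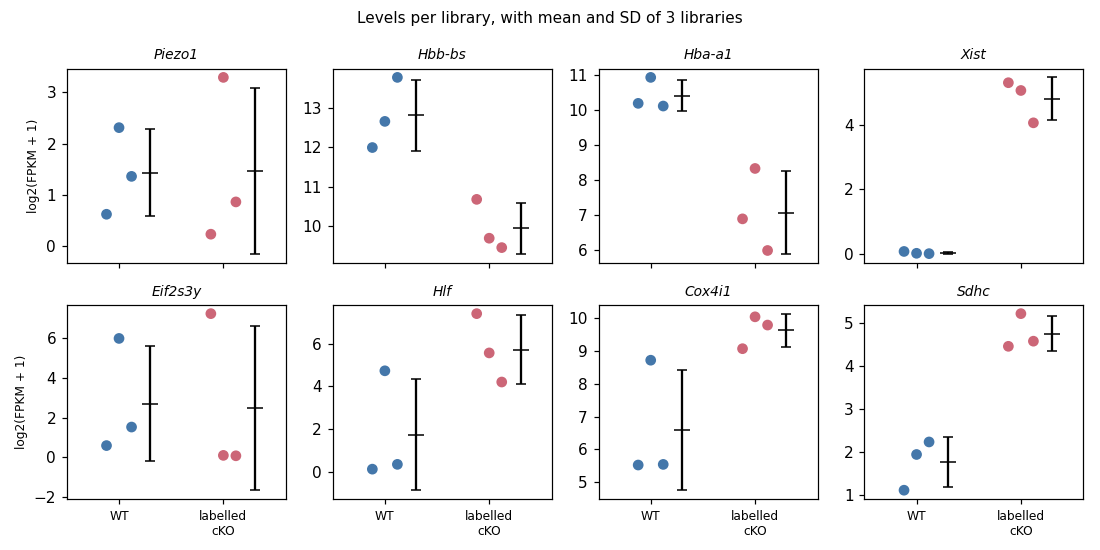
log2(FPKM + 1) of 8 genes, one point per library, with the mean and SD of the 3 libraries of each genotype to the right of the points; the vertical axes differ between panels. Piezo1 overlaps between genotypes, with FPKM 8.81 in labelled cKO 2, while Hbb-bs ranges from 4080 to 14000 in WT and from 702 to 1640 in the labelled cKO.

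Among the HSC identity genes with the smallest p, 3 had their higher levels in WT 2 and the labelled cKO libraries, and stood on 10 to 33 counts each in WT 1 and WT 3. Hlf, a transcription factor of HSCs, had an FPKM of 0.0823, 25.5 and 0.265 in WT against 169, 46.4 and 17.4. Hoxa9 had 0.0957, 35.1 and 0.465 against 125, 38.1 and 33.8, and Myct1 0.532, 34.4 and 0.608 against 113, 79.8 and 84.5. The list of 10 tested genes, 8 of them with a positive difference, had a median log2 difference of 1.12 and did not pass (camera, adjusted p = 0.302). That median was 0.13 without WT 3 and 2.42 without WT 2. It turned to -1.08 without WT 1 and WT 3, which leaves 1 WT library, and to -0.96 with the total count as covariate (both chosen after seeing the data). The quiescence regulators did not pass either (10 genes, median 0.65, adjusted p = 0.925), and in them Trp53 had 0.653, 19.6 and 0.850 in WT against 201, 28.4 and 0.262.

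Lists of stress and signalling genes did not pass the camera test with the settings fixed for it, and some passed under others. The unfolded protein response list had a median of -0.66 over 20 genes (adjusted p = 0.0858). In it, Creld2 had an FPKM of 2.06, 79.9 and 6.12 in WT against 0.910, 0.112 and 0.107, and the disulfide isomerase gene Pdia6 had 3.18, 177 and 6.62 against 1.15, 0.280 and 0.412. These genes stood on 46 to 259 counts in WT 1 and WT 3, against 12 to 166 in the labelled cKO and 7901 and 48039 in WT 2. This list passed with quantile normalization (median -1.60, camera, adjusted p = 0.0209) and without WT 1 (-0.93, adjusted p = 0.0339), but not with an estimated correlation of 0.22 (adjusted p = 0.959). Its median was 0.22 with median-of-ratios scaling. Immediate-early genes had a median of 2.02 over 19 genes (adjusted p = 0.135), with Fosb at 0.226, 9.61 and 0.293 in WT against 59.7, 17.8 and 46.6. They passed with no filter (camera, adjusted p = 0.000135), without a variance trend (0.0325) and without WT 1 (0.0075), but not with an estimated correlation of 0.21 (0.959). The medians were 2.38 for 5 NF-kB and inflammatory genes (adjusted p = 0.430), 1.52 for 10 heat shock genes (0.586), 1.67 for 7 genes of MAPK output (0.925), -0.41 for 8 p53 targets (0.401), -0.87 for 8 apoptosis regulators (0.302) and 0.04 for 17 interferon response genes (0.925). Calcium signalling, with 12 tested genes, had a median of 0.48 (adjusted p = 0.817), and its calcineurin subunit gene Ppp3r1 had 1.75, 16.4 and 4.58 in WT against 0.701, 0.117 and 0.245. Ppp3r1 stood on 123 and 81 counts in WT 1 and WT 3, against 3822 in WT 2 and 31 to 86 in the labelled cKO. Integrin, focal adhesion and actin genes had a median of 0.81 over 23 genes (adjusted p = 0.925).

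Proliferation, metabolism and growth lists did not pass either with these settings. G1/S and DNA replication genes had a median of 1.16 over 20 genes (camera, adjusted p = 0.723), although Mcm5, of the replicative helicase, had an FPKM of 1.03, 12.3 and 1.81 in WT against 0.286, 0.178 and 0.162. Mitotic genes had -0.11 over 17 (0.618), with Ccna2 (cyclin A2) at 1.69, 60.9 and 2.11 against 0.446, 0.115 and 0.793. MYC targets had 0.79 over 22 (0.925), with Myc at 1.57, 121 and 3.02 against 0.501, 0.0624 and 0.552. Mcm5, Ccna2 and Myc stood on 41 to 150 counts in WT 1 and WT 3 and on 14 to 253 in the labelled cKO. In WT 2 they had 3549, 18001 and 23753, so their differences rest mainly on that library. Ribosomal protein genes had 0.89 over 53 (0.631), mitochondrially encoded transcripts 0.62 over 15 (0.817), glycolysis and hypoxia genes 0.18 over 13 (0.817), lysosome and autophagy genes 0.27 over 18 (0.925), and chromatin and myeloid neoplasia genes -0.30 over 7 (0.631). The ribosomal list passed with no filter (camera, adjusted p = 0.00226) and without WT 1 (0.00246), and the mitochondrially encoded list with no filter (0.0458). Neither passed with an estimated correlation (0.959 for each), and without WT 3 both turned, to medians of -0.44 (0.157) and -0.08 (0.895). The median over all tested genes was 0.58 on this scale. Camera, which sets a list's moderated statistics against those of the other genes, gave a downward direction to 7 lists with a positive median and mean: progenitor, calcium, integrin, glycolysis, MYC, MAPK and lysosome genes. The medians of integrin, MYC and MAPK genes lay above 0.58. Megakaryocyte genes had a median of -0.06 and a mean of 0.34.

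**Figure D4:**
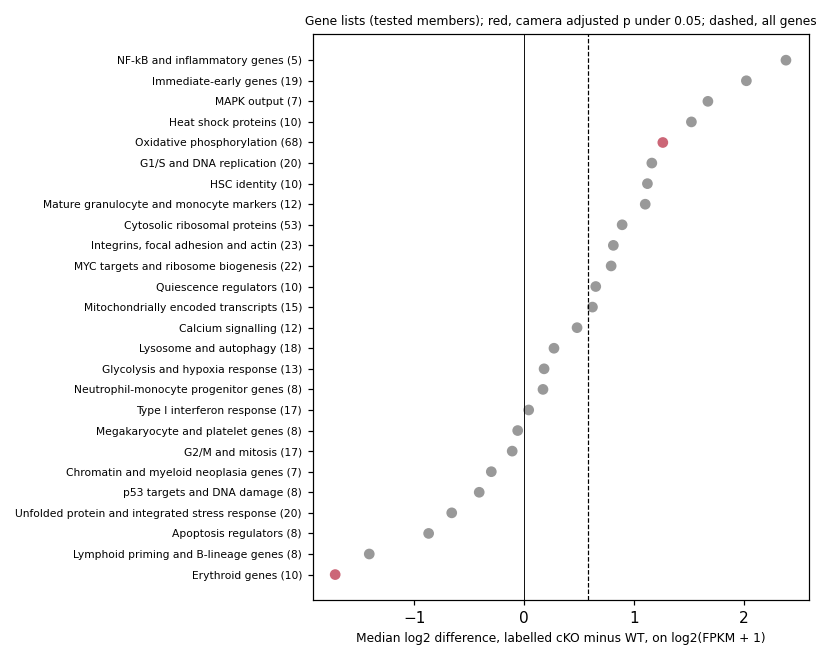
Median log2 difference of each tested gene list on the log2(FPKM + 1) scale, labelled cKO minus WT, with the number of tested members in brackets; the dashed line is the median of all tested genes, 0.58. The 2 lists called by camera, in red, lie at -1.72 (erythroid) and 1.26 (oxidative phosphorylation).

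Markers of other marrow cells were present in several libraries. Mature granulocyte and monocyte markers averaged 5.49 on the log2(FPKM + 1) scale in labelled cKO 2 and 4.19 in WT 1, against 1.42 to 3.22 in the other libraries, with Ngp, a neutrophil granule protein gene, at an FPKM of 4020 in labelled cKO 2 and 4.49 in WT 2. Their list had a median log2 difference of 1.10 over 12 genes (camera, adjusted p = 0.817), and it passed without WT 1 (median 1.63, adjusted p = 0.00767). It turned to -0.82 without labelled cKO 2 (0.19) and to -0.15 without WT 2 (0.204), and did not pass with an estimated correlation of 0.50 (0.959). Lymphoid and B-lineage genes had -1.41 over 8 (adjusted p = 0.0858), with Cd79b, of the B cell receptor, at 3.06, 85.8 and 6.50 in WT against 1.12, 0.356 and 0.271, and passed without WT 1 (adjusted p = 0.0292) but not with an estimated correlation of 0.04 (0.959). Their median turned to 1.20 at a mean FPKM of at least 5. Cd79b stood on 95 and 52 counts in WT 1 and WT 3, against 8891 in WT 2 and 31 to 61 in the labelled cKO. Neutrophil and monocyte progenitor genes had 0.17 over 8 (0.770) and megakaryocyte genes -0.06 over 8 (0.835), with the integrin gene Itga2b at 0.333, 7.21 and 0.306 against 177, 16.6 and 28.2. None of the T and NK cell markers passed the expression filter, but the highest FPKM of any of them was 41.5, 9.54 and 96.5 in WT 1, 2 and 3 and 80.0, 0.247 and 0.425 in labelled cKO 1, 2 and 3. Lck, a kinase of T cell receptor signalling named after its values were seen, had 41.5, 0.973 and 96.5 in WT against 0.286 or less. Mean levels of the 8 marker lists gave exact permutation p-values of 0.1 to 0.8 between genotypes (adjusted p of at least 0.64; n = 3 per genotype).

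Sex-linked genes differed between libraries. Xist, the noncoding RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), had an FPKM of 0.0481, 0.00736 and 0 in WT and 38.6, 32.5 and 15.7 in the labelled cKO (two-sided exact permutation p = 0.1, the smallest possible; edgeR, adjusted p = 0.692). Eif2s3y, on the Y chromosome, had 62.5 in WT 2 and 150 in labelled cKO 1, and 1.87 or less in the other libraries. Uty had 9909 counts in labelled cKO 1, and Ddx3y 1386 in labelled cKO 3.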

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

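Alternatives without WT 1 and WT 3, with the total count as covariate, with count floors, with filterByExpr, with counts divided by 4, with TMM factors or one mean dispersion in DESeq2, with camera on counts and without globin genes were chosen after seeing the data. Unless a reason is given, the cause was not tested. edgeR called 0 genes (287 at an unadjusted p under 0.05), and the count stayed at 0 in limma under each pseudocount, scaling and variance setting, in edgeR with median-of-ratios scaling, with mitochondrial and ribosomal protein genes removed, with counts divided by 4, with the total as covariate, with counts below 100 set to 0, with counts at or below the 95th percentile of 73 olfactory and vomeronasal receptor genes set to 0, without each library in turn (0 to 0), and at an adjusted p of 0.10. It was 298 with DESeq2, 345 with DESeq2 and TMM factors, 204 with one mean dispersion, 163 with no filter, 9 with filterByExpr, 2 at a mean FPKM of at least 5 (Btrc and Atcay, both from WT 3 alone) and 1 without WT 1 and WT 3 (S100a8, with an FPKM of 251 in WT 2 against 625, 22000 and 2660, where the left-out WT 1 had 14900); these genes were chosen after their values were seen. Without WT 1 and WT 3 the WT arm holds 1 library, which is assumed to vary like the labelled cKO libraries. Unadjusted p under 0.05 ranged from 155 to 705 genes over the fits without one library. Positive fold changes made up 67.9% with TMM (median 1.10) and 57.2% with median-of-ratios scaling (median 0.52). Deviations of same-numbered libraries from their genotype means correlated at 0.13, 0.15 and -0.16. With 3 libraries per genotype this cannot show whether equal numbers belong together, and the labels do not say. The replicate block gave 0 genes and 0 lists. Robust variance moderation was not run for the lists, as camera has no such option.

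Gene lists called numbered 2, and 5 with no filter. They numbered 1 with median-of-ratios scaling, array weights, the total as covariate, counts below 100 set to 0 or the erythroid list without globin genes. They numbered 0 with mitochondrial and ribosomal protein genes removed, the replicate block, an estimated correlation, fry, ranks or counts. With 1 library left out, the number ranged from 0 to 7 (7 without WT 1). Without WT 1 and WT 3 the WT arm holds 1 library, so only medians are given for lists in that fit. Lists that gained a call were immediate-early genes (no filter, no trend, without WT 1), the unfolded protein response (quantile normalization, without WT 1) and mature granulocyte markers (without WT 1). Others were ribosomal proteins (no filter, without WT 1), mitochondrial transcripts (no filter) and lymphoid genes (without WT 1). Without WT 1 and WT 3 the medians were 1.01 for immediate-early genes, -1.64 for the unfolded protein response and 3.22 for mature granulocyte markers. The erythroid list (-1.72) stayed negative but lost its call with median-of-ratios scaling (-0.75), removed gene families (-2.04), array weights (-1.51), counts (-1.28), and, at -1.72, with the replicate block, estimated correlation, fry and ranks; without globin genes its median was 0.33, and without one library -2.21 to -1.48. Oxidative phosphorylation (1.26) lost its call with quantile normalization (0.42), removed families (1.25), counts (0.97), the 100-count floor (1.92) and, at 1.26, with the block, estimated correlation, fry and ranks, and turned to -0.71 without WT 1 and WT 3 and -0.91 with the total as covariate; without one library it ranged from 0.02 to 2.28. Adjusted p over these alternatives ranged from 0.000296 to 0.959 for the erythroid list and from 1.19e-08 to 0.959 for oxidative phosphorylation.

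The Piezo1 level (log2 fold change 1.20) turned to -0.32 with pseudocount 0.1, -0.13 with quantile normalization, -0.17 on the TPM scale, -0.16 with median-of-ratios scaling, the replicate block, DESeq2 and DESeq2 with one mean dispersion, and -0.08 without WT 1 and WT 3; without one library it ranged from -1.65 to 2.06. The difference in detected genes per library (-725.3 at FPKM 1) turned to 703 at FPKM 5 and 1188.3 at 1000 counts. The sample structure, within-genotype minus between-genotype correlation (0.028), ranged from -0.031 to 0.151 without one library. For the named genes that follow, a missing adjusted p was counted as not passing. DESeq2 gave none to 752 of the 4173 genes, some of the named ones among them, so keeping their side there is not a test result. Over 81 named genes, 2098 of 2223 values kept direction and side, 97 passed the threshold, all with DESeq2, and 28 turned: the gene Eif2s3y to -0.23 in limma (also without trend and robust), -1.43 with pseudocount 0.1, -0.38 with quantile normalization, -0.60 on the TPM scale, -0.28 with array weights and -4.53 with the block (-8.51 to 5.84 without one library); the gene Uqcrfs1 to -0.28, -0.94, -0.07, -2.11 and -0.10 with pseudocount 0.1, quantile, TPM scale, array weights and block (-6.30 to 4.37); the gene Nusap1 to -0.80 and the gene Bnip3 to -0.17 with the block (-1.97 to 5.32 and -1.13 to 5.93); the gene Retnlg only without one library (-1 to 7.01). Without WT 1 and WT 3, the gene Ppbp turned to 1.37, the gene Pxn to 2.86, the gene mt-Atp6 to -0.17, the gene Eno1 to 1.77 and the gene Nras to 1.88, and with the total as covariate Ppbp to 0.38, mt-Atp6 to -0.01 and Nras to 0.18.

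Among lists that did not pass, the direction of the test turned with these medians. Without WT 1 and WT 3 they were -0.82 (quiescence), -1.37 (G1/S), -0.56 (integrins), -1.51 (interferon), -0.37 (mitochondrial), -0.22 (glycolysis), -0.29 (ribosomal) and 0.23 (lysosome), and with the total as covariate -0.52 (quiescence), -0.19 (integrins), -0.96 (interferon), -0.29 (mitochondrial), -0.15 (glycolysis), -0.53 (ribosomal), 0.58 (MAPK) and 0.25 (lysosome). With the 100-count floor they were 1.82 (quiescence), 1.39 (progenitor), 0.85 (interferon), 0.62 (mitochondrial), 0.94 (ribosomal) and 2.02 (MAPK). No filter gave -0.37 (mitosis), -0.07 (calcium), -0.26 (integrins), 0.18 (glycolysis), 0.38 (MYC), -0.27 (lysosome) and 0.01 (chromatin), and a mean FPKM of 5 gave 0.89 (calcium), 0.97 (integrins) and 0.21 (interferon). fry, which does not compare with other genes, gave 0.17 (progenitor), -0.06 (megakaryocyte), 0.48 (calcium), 0.81 (integrins), 0.18 (glycolysis), 0.79 (MYC), 1.67 (MAPK) and 0.27 (lysosome). Pseudocount 0.1 gave 0.71 (quiescence), 0.83 (integrins) and 0.20 (lysosome); median-of-ratios scaling 1.89 (integrins), 0.62 (interferon) and 1.35 (lysosome); quantile normalization 0.17 (quiescence) and 0.54 (MAPK); no trend 0.81 (integrins), 0.04 (interferon) and 0.27 (lysosome); ranks 0.04 (interferon) and 1.67 (MAPK); counts 0.61 (integrins), 0.65 (interferon), 2.07 (MAPK) and 1.31 (lysosome); and array weights 1.13 (granulocyte) and 1.76 (MYC). Without one library the medians ranged from 0.39 to 1.64 (quiescence), -0.82 to 2.44 (granulocyte), -0.94 to 0.47 (megakaryocyte), 0.00 to 0.70 (calcium), 0.26 to 1.30 (integrins), -0.55 to 1.72 (interferon), -0.08 to 0.93 (mitochondrial), -0.44 to 1.54 (ribosomal), 0.26 to 1.85 (MYC), 0.57 to 2.18 (MAPK) and -0.13 to 0.66 (lysosome). Other medians changed sign while the direction of the test did not, among them, without WT 1 and WT 3, calcium -1.19, progenitor -1.23, MYC -1.43, MAPK -1.46 and lymphoid 0.03, and with median-of-ratios scaling mitosis 0.69, megakaryocyte 0.61, chromatin 0.64, p53 0.28 and apoptosis 0.02. Depth limits WT 3 most, where 262 genes had at least 1000 counts against 4501 in WT 2.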

Other observations

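The tests in this part on sex-linked genes against the Y chromosome, on mixed sexes, on both erythroid explanations and on the loci of WT 3 were chosen after the results were seen.

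None of the genes in this paragraph passed edgeR's test. Tie1, an endothelial receptor gene also active in stem cells, had an FPKM of 0.285, 0.509 and 0.902 in WT against 46.5, 44.0 and 30.5 in the labelled cKO (edgeR, adjusted p = 0.692). Smad1, which transmits BMP signals, had 0.294, 1.08 and 0.110 against 73.6, 24.6 and 12.8 (edgeR, adjusted p = 0.692). Lamp2, a lysosomal membrane protein gene, had 0.910, 3.29 and 3.02 against 81.0, 63.3 and 22.3, and Spred1, an inhibitor of MAPK signalling, 0.810, 0.308 and 1.10 against 26.4, 12.2 and 37.6. Among HSC identity genes below the expression filter, chosen after their values were seen, Kit had 59.5 in labelled cKO 3 and 2.53 or less elsewhere, and Procr 60.2 in labelled cKO 2 and 3.32 or less elsewhere.

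The counts of genes and lists were set against all 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. The real split gave 287 genes at an unadjusted p under 0.05 in edgeR, and the highest other split gave 1311; 3 of the 10 splits gave as many as the real one. DESeq2 called 298 genes in the real split and 1186 in the highest other, and 2 of the 10 splits gave as many. For gene lists the real value was 2 and the highest other 3, with 7 of the 10 splits at 2 or more. The split with 1311 and 1186 genes set WT 1, WT 3 and labelled cKO 1 against the other libraries, which points to a structure of the samples that is not genotype; those 3 libraries have the lowest totals.

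Xist separated the labels completely, and the first explanation to weigh is a difference in sex. If the labelled cKO libraries had come from females and the WT libraries from males, Y-linked counts (Ddx3y, Eif2s3y, Kdm5d and Uty) should be lower in each labelled cKO library, but the highest summed count, 33748, was in labelled cKO 1, against 59 and 2138 in labelled cKO 2 and 3, 19107 in WT 2, and 106 and 82 in WT 1 and WT 3. Labelled cKO 1 also had 25921 Xist counts, and a candidate explanation for that library is RNA of both sexes. Labelled cKO 3 had 21907 Xist counts beside its 2138 Y-linked ones, against a background median of 33. These raw counts depend on depth. Scaled to a common total count, the Y-linked counts were 30.6 in labelled cKO 3 and 21 in WT 3, close to each other. On that scale they were 1080 in labelled cKO 1, 295 in WT 2, 5.88 in WT 1 and 0.818 in labelled cKO 2. The Y-linked counts do not exclude female RNA in every labelled cKO library, which cannot be told apart from the label. WT 1 and WT 3 had few raw counts of either kind (19 and 0 for Xist). Their totals were the lowest of the WT libraries, so neither library shows a sex. An effect of the genotype on Xist stays open as well, as untested. Chance detection stays open too: 20 genes lay above FPKM 5 in all libraries of one genotype and below 1 in all of the other, 4 of the 10 splits gave at least as many, and the highest other split gave 158.

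Globin genes were lower in the labelled cKO libraries. A low yield of cell RNA in WT 1 and WT 3 could raise the globin share there. It would not account for WT 2: against WT 2 alone the mean log2 difference of the 4 globin genes was -3.08. Against WT 1 and WT 3 the difference was -2.53 and -3.02. The globin values were known when this comparison was chosen, and it rests on 1 library. Low yield therefore stays open for WT 1 and WT 3. RNA carried over from red cells or their precursors, which the HSC sort should remove, stays open. The 13 tested genes of a list of 28 other red-cell genes had a median log2 difference of -0.65, below the 0.58 of all genes. The standard error of their mean was 0.42, taken over genes as if independent, and does not measure the spread between libraries. Only 8 of the 13 lay below 0.58, and 4 of the 13 are also on the erythroid list. Among them, chosen after their values were seen, Alas2 had an FPKM of 40.7, 21.8 and 102 in WT against 15.3, 5.81 and 4.98, and Fth1 40.7, 467 and 76.2 against 305, 499 and 308. An effect of the genotype on erythroid transcripts in HSCs also stays open, as untested.

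A few loci took a large share of WT 3. The 20 loci with most counts there, leaving out mitochondrial, ribosomal protein and globin genes, held 40.3% of its counts, 5.71% of those of WT 1, 1.58% of labelled cKO 1 and 0.272% or less of the other libraries. They were led by Cep162 (5.72%), Nras (4.41%) and Arap3 (3.71%), and included Atp6ap2 (0.787%), named above among the genes lower in the labelled cKO. A product of amplification that does not come from the cells' mRNA might repeat between libraries: the median Spearman correlation over these loci between the other 5 libraries was 0.51, against 0.37 in 1000 random sets of matched genes (0.14 to 0.59), so the test cannot tell this apart from genes of like abundance. Outsized counts in Nras, a gene mutated in myeloid neoplasia, therefore need care: it had an FPKM of 1090, 56.2 and 5900 in WT 1, 2 and 3 and 33.0 to 352 in the labelled cKO.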
